A study of Mus musculus with 31 samples.

How the data were processed

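RNA sequencing was carried out on 31 mouse libraries in 6 groups. Thymocytes of C57BL/6 mice were kept in culture for 2 h with the compound MRL-871 (6 libraries) or with the solvent DMSO (6 libraries). Thymocytes were also taken from mice 2 h after 20 mg/kg MRL-871 (6 libraries) or vehicle (4 libraries). A thymic lymphoma line that carries a Rorc knockout was transduced with the retroviral vector MIGR1 holding Rorc and GFP (6 libraries) or GFP alone (3 libraries), and GFP-positive cells were sorted. Per the labels' protocols, RNA was extracted with RNeasy columns, and libraries were made and sequenced at the BGI with Illumina protocols. The groups were taken from the labels. Replicate numbers were given in accession order and pair no libraries.

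The authors deposited 2 tables of estimated counts, so called because some values are not whole numbers, with 1 value per gene and library. One table held the 22 thymocyte libraries and 32027 features, of which 30809 came from UCSC genes, 1181 from miRBase and 37 from Ensembl, per the file headers and the annotation beside the counts. The other held the 9 cell line libraries and 23483 RefSeq features. The genome build was mm10, per the submitters' processing notes and the annotation. Reads were 50 bases long and paired, and had been filtered against adapter, rRNA, tRNA and spike-in sequences, per the deposited filtering reports. The aligner, the counting tool and the handling of strand were not given in the sources used here. A share of 9.54% of the thymocyte values and 7.45% of the cell line values was not whole. These estimated counts were rounded to whole numbers before any test. The authors' FPKM values for the same libraries were not used, because the tests need counts. Total counts per library (M, 1e6 counts) were 21.1M to 41.5M in the thymocyte table and 17.2M to 22.1M in the cell line table. The mean insert length was 254 bases in the thymocyte libraries and 161 bases in the cell line libraries, so both tables were tested separately and levels in CPM (counts scaled to the normalised library total) were not tested across them.

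The annotation marked 9942 thymocyte features and 4601 cell line features as overlapping another feature, and a further 1860 and 2061 unmarked features also overlapped one by their positions. Reads from overlapping genes cannot be told apart without strand, so marked genes were treated as uncertain and each count was repeated without them. Coordinates are those of the files, 1-based, on mm10. Genes were matched across the tables by gene name and chromosome.

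Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr with the groups, and the quasi-likelihood F test. Benjamini-Hochberg adjustment ran over all genes tested, at a threshold of 0.05, and every adjusted p of a gene comes from this test unless another is named. Each fit held only the libraries of its comparison. The submitters' sample numbers fall in 2 separate ranges, which split the in vitro libraries into series A (lower numbers) and series B (higher numbers), each with 3 MRL-871 and 3 DMSO libraries, and the series entered the in vitro fit as a covariate. In vivo, every vehicle library had a lower sample number than every MRL-871 library. An effect that follows number order could therefore not be told apart from the treatment there. The difference between the in vitro and the in vivo effect was the interaction in a joint fit of the 22 thymocyte libraries. Standard errors were computed from the log2 fold change and its F statistic. Means and SDs are in CPM over the libraries of a group, normalised within the comparison. Levels beside the interaction and in the plot of single genes per library come from the 22 thymocyte libraries normalised together, and differ slightly.

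The tests, the named genes and 29 gene lists were chosen before the data were examined. The rule for named genes took Rorc, Rora, Bcl2l1, Rag1, Rag2, Cd4, Cd8a, Arntl, Npas2, Nr1d1 and Cry1 in every comparison. It added the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 2, and up to 4 members of each list by smallest p. For the interaction it took 5 genes per direction by smallest p, and for overlaps the 10 shared genes whose larger p was smallest. The lists covered recombination machinery, TCR alpha variable genes, the BCL2 family, double-positive thymocytes, double-negative thymocytes and Notch, positive selection and TCR signal, mature thymocytes, TH17 and RORγt effectors, the circadian clock, cholesterol synthesis, LXR targets, glycolysis, DNA replication, mitosis, p53 targets, heat shock, ER and integrated stress, immediate early genes, glucocorticoid response, interferon response, E and ID proteins, markers of B cells, of myeloid and dendritic cells, of thymic stroma, of erythroid cells and of NK and innate lymphoid cells, ribosomal protein genes, mitochondrially encoded genes and replication histone genes.

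Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The tests were repeated with the correlation estimated per list, and with fry. Overlaps between comparisons were tested with a 2-sided Fisher's exact test per direction among genes tested in both, beside the number that independent lists would share. The 100 most significant falls or rises of 1 comparison were also tested as a set in another comparison with camera. No libraries are shared between the compared experiments.

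The gene test and the list test with the preset correlation were first tested on simulated data with 200 genes changed by known folds. These data were drawn with the library sizes and spread of each comparison, and with a mean share per gene pooled over its libraries. They held no baseline difference between groups, series, or culture and animal. For the interaction, the changes were placed in the in vitro MRL-871 libraries only, with no in vivo effect, so its shares come from a simpler setting than the real fit. The overlap tests, the estimated correlation and fry were not simulated. In the in vitro simulation of 12363 genes, 82.1% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes were recovered, and 3.43% of the calls were false. For the in vivo comparison (12862 genes) these shares were 64.2%, 86.4% and 98.4%, with 5.91% false calls. For the cell line (11324 genes) they were 64.2%, 84.8% and 98.4%, with 3.91% false calls. For the interaction (12991 genes) they were 59.7%, 87.9% and 92.4%, with 4.57% false calls. In each simulation, 1 list of 15 genes raised 1.5-fold was called and 0 of 39 unchanged lists were called. Simulated genes were drawn independently of each other, so this does not show how the list test behaves for correlated genes. In the real in vitro data the estimated correlation was 0.844 for mitochondrially encoded genes and 0.52 for ribosomal protein genes.

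Alternatives covered DESeq2 size factors in the edgeR fit, no filter on low counts, the DESeq2 1.42.0 Wald test, no series covariate, each series alone, all 22 thymocyte libraries in 1 fit, an estimated correlation for lists, and leaving out each in vivo or cell line library in turn. Further alternatives were chosen after seeing the data and left out features marked as overlapping, in vitro DMSO library 1, in vitro MRL-871 libraries 4 and 5, in vivo MRL-871 libraries 2 and 6, or cell line GFP library 3 with Rorc library 5. Replicates were compared pairwise by a chi-square test of their counts over genes, and the lowest chi-square per degree of freedom between libraries of a group was 5.07, so no library was counted as a duplicate.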

Results

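Gene expression was measured by RNA sequencing in mouse thymocytes treated with MRL-871, a small-molecule inhibitor of the nuclear receptor RORγt, and in a thymic lymphoma line given RORγt. RORγt is encoded by Rorc and is most abundant in immature CD4+CD8+ (double-positive) thymocytes. Cultured thymocytes comprised 6 libraries with MRL-871 (21.5M to 41.5M counts per library) and 6 with DMSO (21.1M to 22.9M). Thymocytes from animals comprised 6 libraries after MRL-871 (26.3M to 30.0M) and 4 after vehicle (22.6M to 28.1M). The Rorc-knockout line comprised 6 libraries with the Rorc vector (17.2M to 22.1M) and 3 with the GFP vector (19.3M to 20.7M). The labels do not say that libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Values are CPM, given as mean ± SD over the libraries of a group.

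The first comparison asked which transcripts changed within 2 h of MRL-871 in cultured thymocytes. Bcl2l1, which encodes the anti-apoptotic protein Bcl-xL and spans mm10 chromosome 2 from 152780668 to 152831682, fell 5.91-fold, from 189.7 ± 22.2 in DMSO to 32.2 ± 3.48 with MRL-871 (n = 6 each, log2 fold change -2.56 ± 0.08 SE, edgeR adjusted p = 7.3e-12). Its log2 change was -2.48 in series A and -2.67 in series B, the lower and the higher range of the submitters' sample numbers, each with 3 libraries per treatment. Arntl, which encodes the clock activator BMAL1 (chromosome 7, 113207465 to 113314126), fell from 114 ± 12.3 to 38.7 ± 5.58 (-1.56 ± 0.09, adjusted p = 1.2e-08; -1.41 and -1.74 within the series). The nuclear receptor gene Nr1d1 (chromosome 11, 98767935 to 98775242) fell from 6.62 ± 0.639 to 1.61 ± 0.407 (-2.05 ± 0.14). The clock repressor gene Cry1 (chromosome 10, 85131700 to 85185054) fell from 107.5 ± 6.75 to 67.4 ± 6.52 (-0.68 ± 0.06). Rorc itself (chromosome 3, 94372826 to 94398239) was at 164 ± 14.8 and 145 ± 22.7 and did not pass the test (-0.19 ± 0.07, adjusted p = 0.256). Neither did Rora (-0.07 ± 0.13, adjusted p = 0.943) or Npas2, a paralogue of Clock (-0.15, adjusted p = 0.934).

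Of 12362 genes tested in vitro, 442 were called, 125 higher and 317 lower, and all 58 with a change of at least 2-fold were lower. Series A alone called 104 genes, 7 higher and 97 lower, of which 103 were among the 442, and series B alone called 236, 44 higher and 192 lower, of which 230 were. DESeq2 called 185 higher and 383 lower. Among called genes with a mean log2 CPM of at least 2, the largest falls beside Bcl2l1 and Nr1d1 were those of Xrra1 (15.03 ± 3.4 to 1.61 ± 0.318, log2 -3.21), Rbm24, an RNA-binding protein gene (-2.68), and Esrp2, a splicing regulator (-2.39). Plekhf1 (-2.35), E130304F04Rik (-2.28), Xkrx (52.7 ± 5.86 to 11.3 ± 1.58, -2.23), 2010015L04Rik (-1.97) and the integrin gene Itga3 (-1.80) followed. Rises were smaller. By the same limit on CPM, the largest were those of the phosphatase gene Dusp14 (0.78), Gcnt3 (0.73), Agpat9 (0.71) and B3gnt8 (0.67). They were followed by those of the growth regulator Myc (15.5 ± 1.10 to 24.2 ± 3.76, 0.63 ± 0.09, adjusted p = 0.00043), Cdk5r1 (0.63) and Mrgpre (0.60). The adhesion receptor gene Cd44 (49.0 ± 4.00 to 72.96 ± 5.88, 0.57 ± 0.07), Dfna5 (0.55) and Bambi-ps1 (0.55) also rose. Of these 10 rises, that of Cd44 was called in every alternative, and each of the other 9 was lost in 1 or 2 of them (Myc in series A alone, 0.50, adjusted p = 0.144).

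Among 18 tested members of the circadian clock list, 5 fell and 0 rose (7 fell when adjusted over the list alone). They were Arntl, Nr1d1, Cry1, the transcription factor gene Hlf (-1.82 ± 0.23, adjusted p = 9.5e-05) and Clock (-0.44 ± 0.10, adjusted p = 0.021). The list was lower than other genes by camera (adjusted p = 2.5e-07), a call lost with an estimated correlation (adjusted p = 0.244 with an estimated correlation). Arntl, Nr1d1, Rag1, Rag2, Rorc and Xrra1 are among the named genes that carry the overlap mark in the thymocyte table. So are Esrp2, Xkrx, 2010015L04Rik, Agpat9, B3gnt8 and Mcl1. Among the in vivo changes given below, Tube1, Slc7a11, H2-Q1, Grasp and Ptrh1 also carry it. Without strand, reads of marked genes cannot be separated from those of their neighbours. Of 41 called named genes in vitro, 27 carry no mark, and 0 of the 27 lost the call when marked features were left out. Their own counts do not change in that fit, so this says nothing about the marked genes. Thra, which overlaps Nr1d1, was at 23.7 ± 1.57 and 26.2 ± 1.67 (0.15 ± 0.06, adjusted p = 0.351). B230118H07Rik, which overlaps the Rag genes, fell by 0.61 on the log2 scale (adjusted p = 0.020). Both partners were looked up after the values of the named genes were seen.

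In the double-positive thymocyte list, 5 of 13 members fell and 0 rose (8 fell and 1 rose when adjusted over the list alone). Ets2, a transcription factor gene, fell from 762.5 ± 72.0 to 425 ± 62.8 (-0.84). Rag1 and Rag2, which encode the recombinase that assembles antigen receptor genes, fell from 4020 ± 637 to 2900 ± 499 (-0.48 ± 0.11, adjusted p = 0.020) and from 142 ± 21 to 92.3 ± 14.9 (-0.63 ± 0.10, adjusted p = 0.0013). The coreceptor genes Cd4 (chromosome 6, 124864693 to 124888209) and Cd8a fell by 0.27 (adjusted p = 0.014) and 0.25 (adjusted p = 0.0029) on the log2 scale. The list was lower by camera (adjusted p = 7.5e-07; adjusted p = 0.244 with an estimated correlation). Several of these calls were lost when series A was fitted alone (Rag1 -0.61, adjusted p = 0.161; Rag2 -0.76, adjusted p = 0.065; Cd4 -0.25, adjusted p = 0.544; Cd8a -0.27, adjusted p = 0.162). In series B alone Rag1 (-0.36, adjusted p = 0.26), Cd4 (-0.31, adjusted p = 0.068) and Cd8a (-0.24, adjusted p = 0.127) were not called, while Rag2 was (-0.51, adjusted p = 0.022).

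Smaller groups moved in both directions in vitro. In the BCL2 family, 2 of 16 members fell, Bcl2l1 and the anti-apoptotic Mcl1 (515 to 444, -0.21), and 2 rose, the pro-apoptotic Bmf (159 to 225, 0.50) and Bid (26.7 to 34.7, 0.38). Mcl1 was not called in series A alone (-0.26, adjusted p = 0.153) or series B alone (-0.18, adjusted p = 0.357). Nor was Bid (0.36, adjusted p = 0.279 and 0.39, adjusted p = 0.322). Bmf was called in series B alone (0.53, adjusted p = 0.025) but not in series A (0.46, adjusted p = 0.114). The counts were the same when adjusted over the list alone, and the list was not called (camera adjusted p = 0.766). Recombination machinery had 3 of 12 members lower, Rag1, Rag2 and the chromatin protein gene Hmgb1 (2524 to 2039, -0.31), and missed the threshold as a list (adjusted p = 0.0865; 3 fell when adjusted over the list alone). In the double-negative and Notch list, Cd44 and Notch1 (0.32, lost in 4 of 9 alternatives with adjusted p up to 0.491) rose and Ptcra, the pre-TCR alpha chain gene, fell (-0.63), with the same counts when adjusted over the list alone and camera adjusted p = 0.376. Id3, an inhibitor of E proteins, rose (0.49) while Id1, of the same family, fell (-1.32). Series A alone lost Hmgb1, Ptcra and Id1, with adjusted p up to 0.0731, 0.193 and 0.118, and series B alone lost Id1. Of 9 TCR alpha variable genes, 0 were called (2 fell when adjusted over the list alone), and the list was lower by camera (adjusted p = 0.0034; adjusted p = 0.759 with an estimated correlation). Ribosomal protein genes (0 of 81 called, median log2 change 0.04, camera adjusted p = 0.0010), mitochondrially encoded genes (0 of 14, adjusted p = 0.013) and ER and integrated stress genes (0 of 13, adjusted p = 0.014) were higher as lists, with 0 called when adjusted over the list alone. None of these 3 calls held with an estimated correlation (adjusted p = 0.852, adjusted p = 0.852 and adjusted p = 0.759 with an estimated correlation). By fry, 3 lists were called in vitro, the clock list (adjusted p = 0.0032), the double-positive list (adjusted p = 0.011) and the BCL2 family (adjusted p = 0.011). Fry tests whether a list moves on balance against no change, and not against other genes, so a few large changes can call a list. The BCL2 family, with 2 members lower, 2 higher and a median log2 change of 0.03, did not move one way. Regrouping the libraries gave at least 6 called lists in 69 of 100 splits, the real one included.

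The in vivo comparison asked which transcripts changed in thymocytes 2 h after 20 mg/kg MRL-871. Bcl2l1 fell 4.08-fold, from 218 ± 15.9 (n = 4) with vehicle to 53.4 ± 3.77 (n = 6) with MRL-871 (-2.03 ± 0.06, edgeR adjusted p = 2.0e-10). Arntl fell from 94.95 ± 6.63 to 32.4 ± 4.28 (-1.55 ± 0.09, adjusted p = 5.9e-08), and Nr1d1 fell from 5.42 to 1.51 (-1.85 ± 0.16). Cry1 fell from 96.5 ± 5.09 to 45.2 ± 3.83 (-1.09 ± 0.07) and Npas2 from 3.26 ± 0.16 to 0.859 ± 0.338 (-1.92 ± 0.25, adjusted p = 0.00024). Cd4 fell from 874 ± 65.6 to 487 ± 36.8 (-0.84 ± 0.07, adjusted p = 1.9e-06). Rorc fell from 245 ± 25.5 to 198 ± 15.1 (-0.31 ± 0.07, adjusted p = 0.038), a call that 8 of 15 alternatives lost (adjusted p from 0.0054 to 0.205). Rag1 (4126 ± 243 and 3492 ± 942, adjusted p = 0.602), Rag2 (260 and 217, adjusted p = 0.398), Cd8a (1817 ± 144 and 1452 ± 186, adjusted p = 0.104) and Rora (adjusted p = 0.945) did not pass the test.

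Of 12878 genes tested in vivo, 332 were called, 33 higher and 299 lower, and of 64 with a change of at least 2-fold, 63 were lower. The number of rises depended on the method, with 94 by DESeq2 (of 490 called), 70 in 1 fit of 22 libraries (of 413), 79 without MRL-871 libraries 2 and 6 (of 403) and 15 without features marked as overlapping (of 204). Xrra1 (11.1 ± 2.34 to 0.817 ± 0.232, -3.75), 2010015L04Rik (-3.07), Leprel4 (-2.78), the orphan receptor gene Gpr162 (61.5 ± 6.57 to 14.1 ± 2.51, -2.12), E130304F04Rik (-2.06), and the tubulin gene Tube1 (-2.02) were, with Bcl2l1, among the 10 largest falls of called genes with a mean log2 CPM of at least 2. So were Plekhf1 (-1.96), the semaphorin receptor gene Plxnd1 (347 ± 21.3 to 93.3 ± 16.3, -1.89) and the cystine transporter gene Slc7a11 (64.9 ± 4.00 to 18.2 ± 3.71, -1.84). By the same limit, the largest rises were those of H2-Q1 (0.63), Bambi-ps1 (0.61), Grasp (0.58), Ptrh1 (0.54) and Tnfsf14 (0.52). Smaller ones among the first 10 were those of Itm2a (362 ± 16.3 to 520 ± 103, 0.52 ± 0.12, adjusted p = 0.033), B3gnt8 (0.52), the transporter gene Abcc5 (136 ± 4.86 to 192 ± 15.7, 0.50 ± 0.06), Dusp4 (0.48) and Adamtsl2 (0.46). Calls of Adamtsl2, Tnfsf14, Dusp4 and Itm2a were lost in 12, 7, 6 and 5 of 16 alternatives, with adjusted p up to 0.144, 0.154, 0.118 and 0.138.

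The circadian clock list had 7 of 17 members lower and 1 higher (8 lower and 1 higher when adjusted over the list alone). Beside Arntl, Npas2, Nr1d1 and Cry1, Clock (-0.38), Nfil3 (-0.82) and Rorc fell, and Tef, a transcription factor gene of the clock output, rose (0.30, adjusted p = 0.028). The list was lower by camera (adjusted p = 1.6e-07) and was the only list of the 3 comparisons called with an estimated correlation (adjusted p = 0.011 with an estimated correlation). In the double-positive list, 4 of 13 members fell, Cd4, Ets2 (544 to 319, -0.77), Aqp11 (-0.35) and Rorc, and 0 rose (6 fell and 2 rose when adjusted over the list alone). Its camera adjusted p was 0.00036 (adjusted p = 0.882 with an estimated correlation). In the BCL2 family, Bcl2l1 fell and Bid rose (52.2 to 66.6, 0.35, adjusted p = 0.0031) among 16 members, with 2 risen and 1 fallen when adjusted over the list alone and camera adjusted p = 0.809. By fry, 3 lists were called in vivo, the clock list (adjusted p = 1.7e-05), LXR targets (adjusted p = 0.0047) and the BCL2 family (adjusted p = 0.019).

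Markers of B cells and of myeloid and dendritic cells were lower as lists after MRL-871 in vivo, and both calls were lost with an estimated correlation. Lists of NK and innate lymphoid (median 0.11), thymic stroma (0.11) and erythroid markers (-0.05) were not called (camera adjusted p = 0.226, 0.744 and 0.368). Of 9 B cell markers, 1 fell, Cd79b (-0.41, adjusted p = 0.038, lost in 8 of 16 alternatives with adjusted p up to 0.163), and the same 1 when adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.882 with an estimated correlation). Of 17 myeloid and dendritic markers, 0 were called either way (median -0.23, camera adjusted p = 0.041; adjusted p = 0.882 with an estimated correlation). LXR targets, which act in sterol export and lipid synthesis, had 0 of 9 members called (2 fell when adjusted over the list alone; camera adjusted p = 0.041; adjusted p = 0.365 with an estimated correlation). Ribosomal protein genes (0 of 80 called, median 0.09, adjusted p = 9.5e-05) and mitochondrially encoded genes (0 of 14, adjusted p = 0.041) were higher as lists, with 0 called when adjusted over the list alone, and both calls were lost (adjusted p = 0.882 for each with an estimated correlation). MRL-871 library 6 stood apart, with 1.51% of reads removed as rRNA against 0.189% to 0.266% in the other treated libraries and the highest B cell (log2 CPM 2.89) and myeloid (4.55) marker medians among them. Myeloid medians were 3.19 to 3.65 in the other treated libraries and 3.75 to 4.00 with vehicle. Without library 6, 6 of the 17 myeloid markers were called as fallen, among them Csf1r (-0.71, adjusted p = 0.000297), C1qb (-0.65, adjusted p = 0.00283), C1qc (-0.68, adjusted p = 0.0068) and Cd68 (-0.74, adjusted p = 0.0405), and 10 without libraries 2 and 6. Uniquely paired reads made up 89.6 ± 0.414% with MRL-871 and 90.3 ± 0.447% with vehicle (exact permutation p = 0.0095, 0.127 after BH over 16 tests of library measures). Leaving out MRL-871 libraries 2 and 6 gave 403 called genes and 4 called lists in place of 7. Other groupings of these 10 libraries gave at least 7 called lists in 61 of 100 splits, the real one included.

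**Figure D1:**
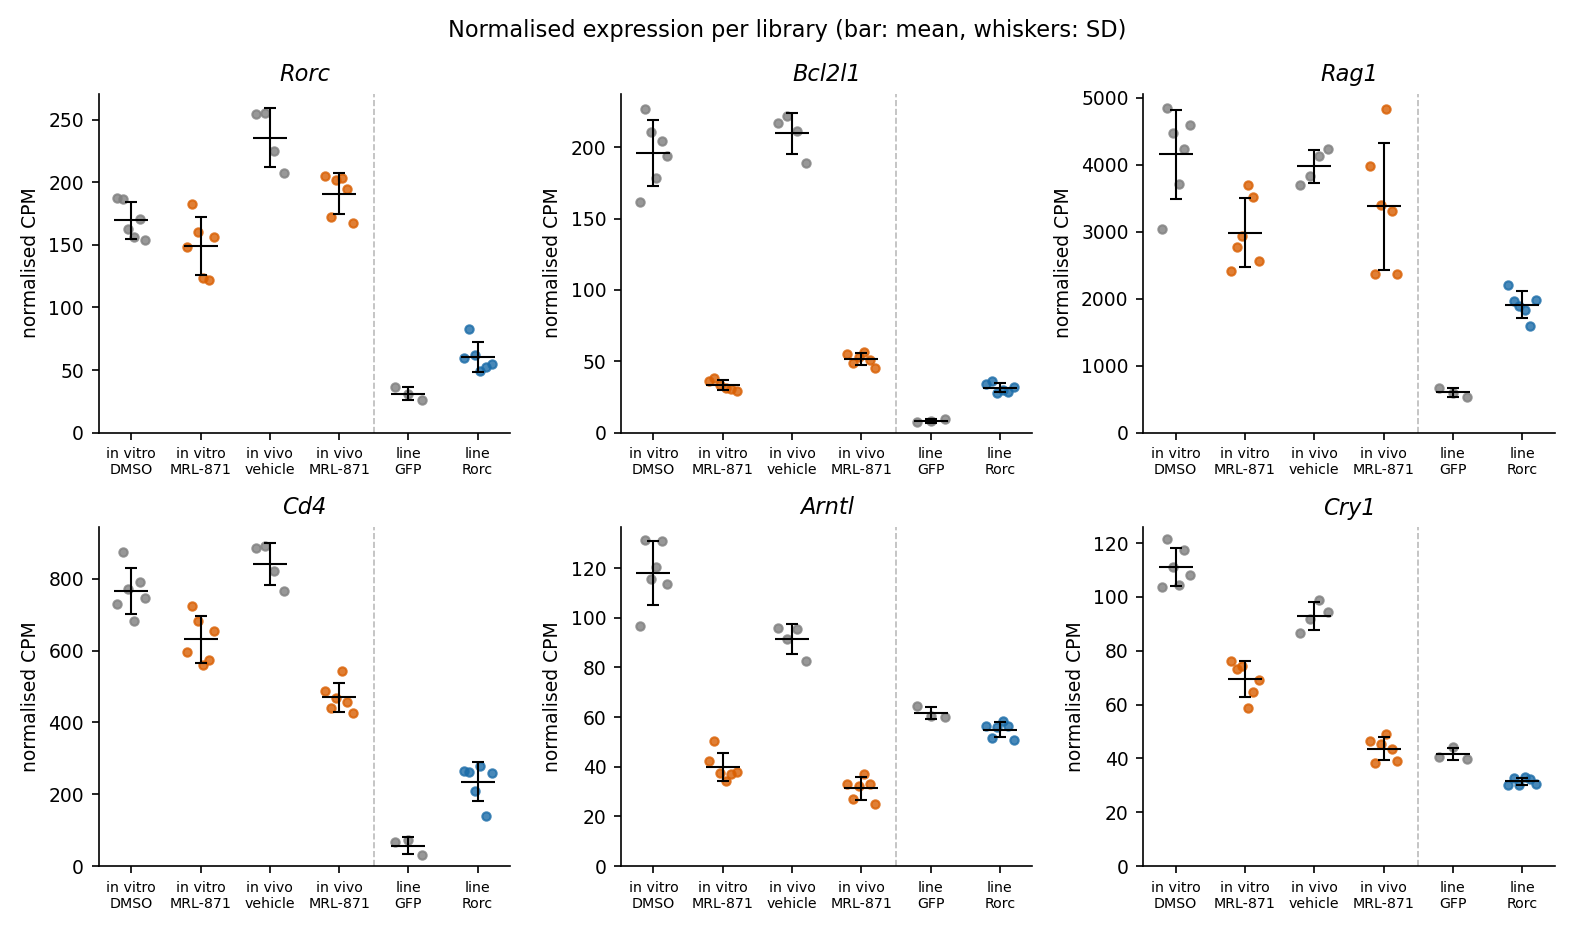
Normalised expression in CPM (vertical axes) of Rorc, Bcl2l1, Rag1, Cd4, Arntl and Cry1 in each library (points), with bars at the group mean and whiskers of 1 SD, for controls (grey), MRL-871 (orange) and the Rorc vector (blue); the dashed line separates tables that were normalised separately. All 22 thymocyte libraries were normalised together here, so levels differ slightly from those of the separate fits. Bcl2l1 was at 29.4 to 38.4 in the MRL-871 and 161.7 to 226.8 in the DMSO libraries in vitro, at 45.2 to 56.3 against 189.1 to 221.9 in vivo, and at 28.0 to 35.9 with Rorc against 7.18 to 9.77 with GFP in the cell line.

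A further comparison asked whether both treatments changed the same genes. Among 12178 genes tested in both experiments, 171 fell in both (7.6 for independent lists, Fisher's exact 2-sided p = 8.0e-212), 10 rose in both (0.3, exact p = 5.3e-13) and 0 were called in opposite directions. These exact tests, and those against the line below, treat genes as independent units, so their p-values do not measure replication between experiments. The shared rises numbered 19 by DESeq2, 25 without in vivo MRL-871 libraries 2 and 6, and 7 without features marked as overlapping. The 10 shared genes with the strongest evidence were Bcl2l1, E130304F04Rik, Xrra1, Gtf2h4, Arntl, Xkrx, Jup, Lipa, Leprel4 and Uspl1, all lower. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.456 and a Spearman correlation of 0.20. The 100 most significant in vitro falls were lower in vivo as a set, with 83 called as fallen and 0 as risen (camera p = 1.3e-05 with an estimated correlation). Of the 100 most significant in vitro rises, 9 were called as risen in vivo and 0 as fallen (p = 0.040 with an estimated correlation). Without features marked as overlapping, 120 genes were called in both in the same direction.

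**Figure D2:**
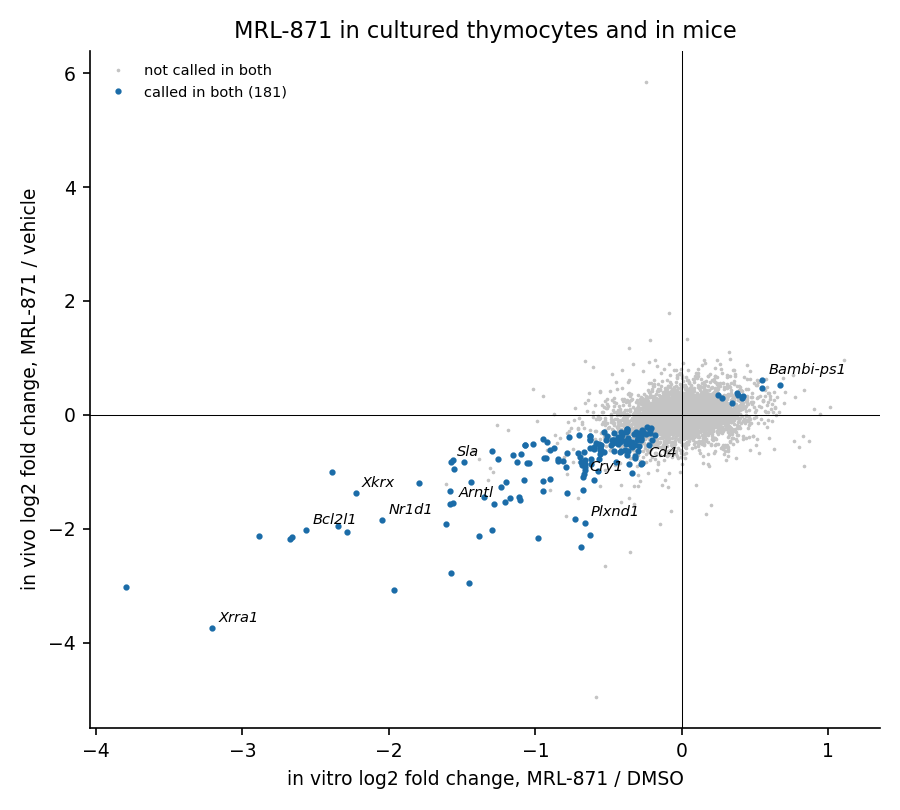
Log2 fold change with MRL-871 in vitro (horizontal axis) against that in vivo (vertical axis), 1 point per gene tested in both experiments, with the 181 genes called in both in blue. All 181 lie in the lower left or upper right quadrant, 171 of them lower in both.

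The size of the effect was compared between culture and animal by the interaction in a joint fit of the 22 thymocyte libraries. Levels given with it come from the joint normalisation and differ slightly from those of the separate fits. Of 13127 genes, 58 differed, 42 with a higher log2 change in vitro than in vivo and 16 with a lower one. Bcl2l1 fell further in vitro (difference -0.54, edgeR adjusted p = 0.013), whereas Cd4 fell further in vivo (0.56, adjusted p = 0.0046). Npas2 (1.77, adjusted p = 0.035) and Cry1 (0.41, adjusted p = 0.0485) also differed, but 8 and 11 of 16 alternatives lost these calls, with adjusted p up to 0.0851 and 0.138. The interaction missed the threshold for Arntl (-0.02, adjusted p = 0.983), Nr1d1 (-0.21, adjusted p = 0.866), Rag1 (-0.25, adjusted p = 0.85), Rag2 (-0.38, adjusted p = 0.651) and Rorc (0.11, adjusted p = 0.865).

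The 5 differences above 0 with the smallest p were those of Cdkl1, Atp10a, Plxnd1, Dab2ip and Slc7a11. Cdkl1, a kinase gene, went from 1.72 ± 0.232 to 0.0513 ± 0.0351 in vivo and from 2.07 ± 0.608 to 1.38 ± 0.559 in vitro (4.36 ± 0.49, adjusted p = 3.3e-05). Atp10a, a phospholipid transporter gene, went from 155 ± 7.38 to 76.6 ± 7.13 in vivo and from 78.4 ± 5.24 to 73.8 ± 10.4 in vitro (0.93, adjusted p = 3.3e-05). Slc7a11 went from 62.5 to 17.6 in vivo and from 253 to 153 in vitro (1.10). Below 0, the smallest p belonged to Sla, an adaptor that dampens TCR signalling (-0.76, adjusted p = 0.00014), Xkrx (-0.86), Tnip1 (-0.52), Leo1 (-0.67) and Cnn3 (-0.77). Among the genes named here, Cdkl1, Dab2ip, Slc7a11, Sla and Xkrx carry the overlap mark, so their differences are uncertain. DESeq2 called 91 differences, 67 above and 24 below 0, and 38 were called without features marked as overlapping, 27 above and 11 below 0. Of 100 groupings of the libraries that were refitted, the real one included, 3 called at least 58 genes and 1 of these called 563.

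The cell line comparison asked which transcripts changed when Rorc was put back. Rorc was at 31.1 ± 5.26 (n = 3) with the GFP vector and 60.2 ± 12 (n = 6) with the Rorc vector (0.95 ± 0.16, edgeR adjusted p = 0.0010), so the knockout control libraries held 51.8% of the level with Rorc. Counts are per gene and do not show which exons were read. Bcl2l1 rose 3.80-fold, from 8.25 ± 1.35 to 31.4 ± 3.26 (1.93 ± 0.13, adjusted p = 3.4e-06). Rag1 (chromosome 2, 101638252 to 101649532) rose from 599 ± 63.3 to 1911 ± 204 (1.67 ± 0.10, adjusted p = 1.9e-06). Rag2 rose from 29.9 ± 4.59 to 105 ± 8.20 (1.82 ± 0.10) and Cd4 from 56.6 ± 23.7 to 235 ± 53.1 (2.05 ± 0.30, adjusted p = 0.00035). Cd8a, at 0.964 ± 1.01 and 3.27 ± 2.44, missed the threshold (1.76 ± 0.70, adjusted p = 0.068). Cry1 fell from 41.5 ± 2.29 to 31.5 ± 1.35 (-0.40 ± 0.06, adjusted p = 0.00052). Arntl fell from 61.7 ± 2.50 to 54.9 ± 3.05 (-0.17 ± 0.06, adjusted p = 0.048), a call that 10 of 14 alternatives lost (adjusted p up to 0.198). Nr1d1 (7.27 and 9.99, adjusted p = 0.058) and Rora (2.12 and 3.37, adjusted p = 0.268) were not called, and Npas2 was too low to be tested.

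Of 11295 genes tested in the line, 4576 were called, 2256 higher and 2320 lower, and 683 changed at least 2-fold, 443 of them higher. With a mean log2 CPM of at least 2, the largest rises were those of Osbp2, an oxysterol-binding protein gene (0.0355 to 20.9), Ankrd63 (0.0177 to 6.31), Rgs16 (0.104 to 9.66), Irf6 (0.153 to 8.77), and Myo1f (0.191 to 10.2). They were followed by the cytokine receptor gene Il4ra (0.697 to 25.3), Gpr162 (2.62 ± 0.185 to 84.5 ± 8.29, 5.01 ± 0.12), the cytokine gene Il10 (1.62 ± 0.978 to 51.0 ± 10.6, 4.95 ± 0.33), Srgap3 and Dysf. By the same limit, the largest falls were those of the somatostatin receptor gene Sstr2 (17.2 ± 0.307 to 0.989 ± 0.443, -4.11), Dlk1 (-4.04), Esm1 (-3.86), and Fgfbp1 (-3.30). Next came the granzyme gene Gzma (132 ± 26.2 to 13.8 ± 5.13, -3.26), the Hedgehog effector gene Gli1 (-2.82), the inhibitory receptor gene Ctla4 (16.8 ± 3.11 to 2.69 ± 0.584, -2.64), Bst1, Naip5 and Dusp4. Dlk1 ranged from 5.62 to 137 across the GFP libraries, and its call was lost without GFP library 3 (adjusted p = 0.459, with 0.00245 the lowest over its alternatives).

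In the double-positive list, 8 of 13 members rose and 2 fell (9 rose and 2 fell when adjusted over the list alone). The 8 include Rorc, the gene on the vector, whose rise was set by the design and which also entered the camera test. The risen members included Rag1, Rag2, Cd4, Ets2 (150 to 442, 1.56), Aqp11 (1.38), Cd8b1 (1.17) and Themis (0.46), and those that fell were the E protein gene Tcf12 (-0.26) and Dntt, the terminal transferase gene (-0.45). The camera adjusted p was 0.0020 (adjusted p = 0.301 with an estimated correlation). Mitosis genes had 11 of 15 members higher (11 when adjusted over the list alone), among them the cyclin gene Ccnb2 (0.74) and the topoisomerase gene Top2a (0.53), with camera adjusted p = 5.7e-05 (adjusted p = 0.436 with an estimated correlation). In the BCL2 family, 6 of 11 members rose and 3 fell (6 and 4 when adjusted over the list alone), with Bad (0.71) and Bmf (0.58) higher and Bcl2 (-0.51) lower beside the rise of Bcl2l1, and the list was not called (camera adjusted p = 0.314).

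With Rorc in the line, ribosomal protein genes had 59 of 76 members lower and 0 higher (63 lower when adjusted over the list alone), with a median of -0.21 (camera adjusted p = 4.7e-16; adjusted p = 0.436 with an estimated correlation). In glycolysis, 11 of 17 members fell, among them the hexokinase gene Hk2 (63.4 to 19.4, -1.70), Pgam1 (-0.71) and Pkm (-0.57), and the phosphofructokinase gene Pfkp rose (0.77). The counts were unchanged when adjusted over the list alone (camera adjusted p = 0.00018; adjusted p = 0.436 with an estimated correlation). Heat shock genes had 6 of 10 members lower and 1 higher by both counts, with the chaperone genes Hspd1 (-0.93) and Hsp90ab1 (-0.69) among the falls (adjusted p = 0.0043; adjusted p = 0.436 with an estimated correlation). ER and integrated stress genes had 7 of 13 lower and 1 higher when adjusted over all genes or adjusted over the list alone. Those that fell included Phgdh (-0.85) and Psat1 (-0.79) of serine synthesis, while the stress-induced mTORC1 inhibitor Ddit4 rose (1.21), and the list had camera adjusted p = 0.029 (adjusted p = 0.462 with an estimated correlation). Cholesterol synthesis genes had 11 of 22 lower and 1 higher (12 and 2 when adjusted over the list alone), with Lss at -0.40 and Pmvk at 0.95 (camera adjusted p = 0.034; adjusted p = 0.667 with an estimated correlation). Of 3 NK and innate lymphoid markers, Gzma and Sox13 (-2.11) fell by both counts (camera adjusted p = 0.034; adjusted p = 0.436 with an estimated correlation). By fry, 13 lists were called in the line, the 8 called by camera and also recombination machinery (adjusted p = 0.00029), the BCL2 family (adjusted p = 0.00080), positive selection (adjusted p = 0.0021), LXR targets (adjusted p = 0.0043) and interferon genes (adjusted p = 0.027). Lists called by fry alone are not set apart from other genes, as 4576 of 11295 genes were called in the line. Other splits of the 9 libraries gave at least 8 called lists in 8 of 84 cases, the real one included. Libraries with Rorc and with GFP also differed in 91.2 ± 0.429% and 92.2 ± 0.395% uniquely paired reads (exact permutation p = 0.024), 1.53 ± 0.167% and 1.15 ± 0.197% reads removed as rRNA (0.048), and 4.30 ± 0.127% and 5.02 ± 0.163% of counts in the 10 highest genes (0.024). After BH over the 16 tests of library measures these were 0.127, 0.173 and 0.127.

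**Figure D3:**
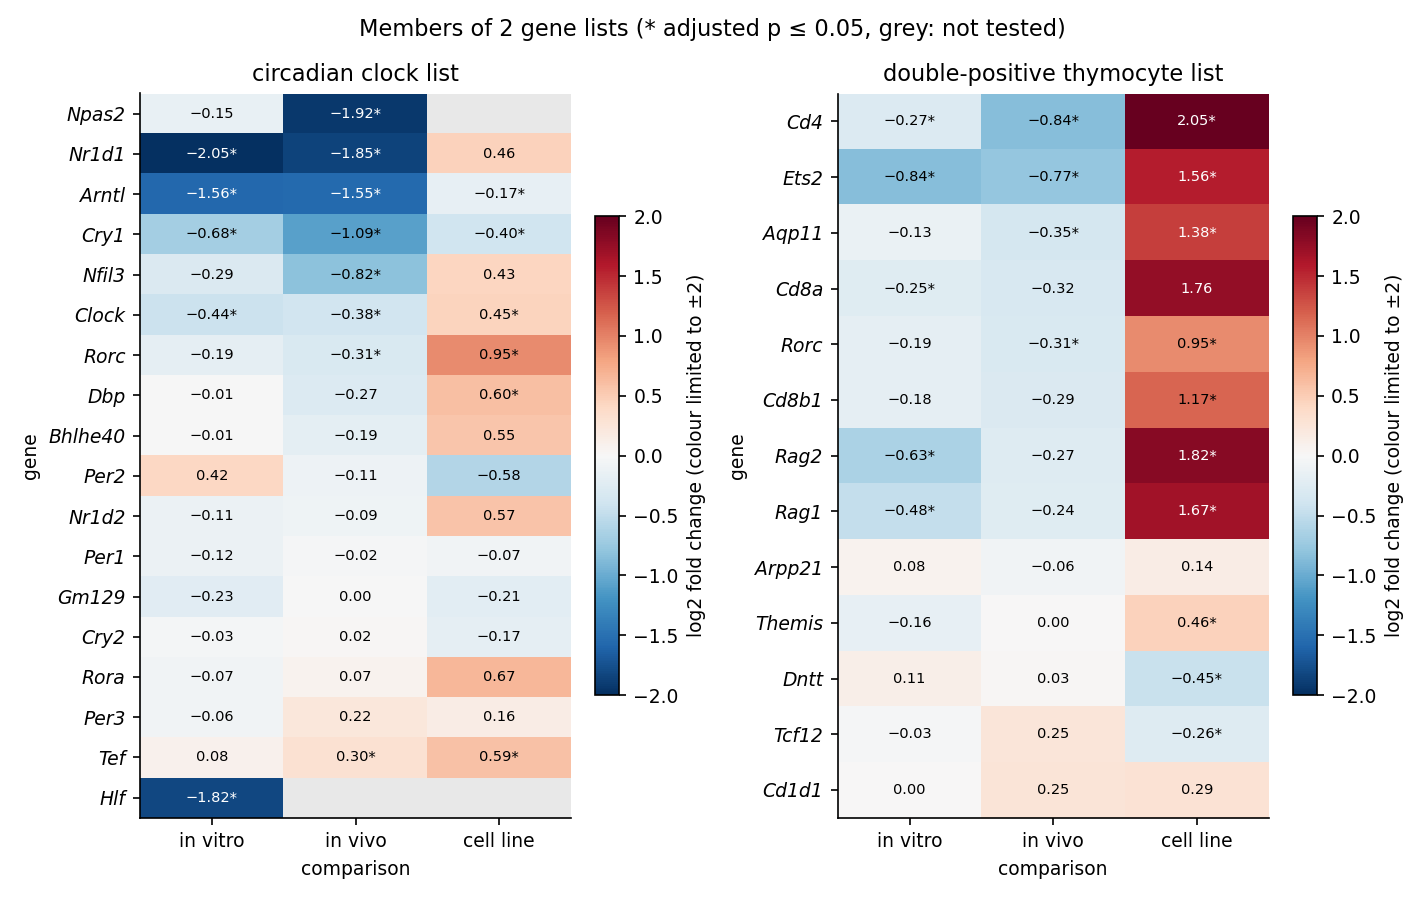
Log2 fold changes (colour scale) of members of the circadian clock and double-positive thymocyte lists in the in vitro, in vivo and cell line comparisons, with an asterisk at an adjusted p of 0.05 or less and grey where a gene was not tested. Arntl is lower in all 3 columns (-1.56, -1.55 and -0.17), while Cd4 is lower in both MRL-871 columns (-0.27 and -0.84) and higher with Rorc (2.05).

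The last comparison asked whether genes moved by the inhibitor moved the opposite way when RORγt was added. Of 247 genes called in vitro and in the line, 208 (84.2%) changed in opposite directions. Among 10368 genes tested in both, 166 fell with MRL-871 and rose with Rorc (56.7 for independent lists, Fisher's exact 2-sided p = 8.5e-48), 42 rose with MRL-871 and fell with Rorc (23.5, exact p = 5.7e-05), 22 fell in both and 17 rose in both. The 42 became 65 by DESeq2 and 27 without features marked as overlapping. Of 192 genes called in vivo and in the line, 173 (90.1%) went opposite ways, 164 lower with MRL-871 and higher with Rorc (52.7, exact p = 2.3e-52) and 9 the reverse (5.6, exact p = 0.15). The reverse group held 36 genes by DESeq2, 24 without in vivo MRL-871 libraries 2 and 6, and 2 without features marked as overlapping. Across genes, which are not independent replicates, the Pearson correlation with the cell line effect was -0.245 in vitro and -0.281 in vivo. The 100 most significant in vitro falls included 63 that rose and 10 that fell with Rorc (camera p = 0.011 with an estimated correlation), and the 100 most significant in vivo falls included 69 and 10 (p = 0.0066 with an estimated correlation). With the correlation estimated, the rises with MRL-871 did not pass as sets, with 38 fallen and 16 risen of 100 from the in vitro comparison (p = 0.0915 with an estimated correlation) and 9 and 2 of 27 from the in vivo one (p = 0.325 with an estimated correlation). Of the 100 most significant rises in the line, 37 fell in vitro (p = 3.0e-05 with an estimated correlation) and 36 in vivo (p = 0.0014 with an estimated correlation). With the correlation estimated, the 100 most significant falls in the line did not pass in vitro (p = 0.31 with an estimated correlation) or in vivo (p = 0.158 with an estimated correlation). Without features marked as overlapping, 108 genes were called in vivo and oppositely in the line.

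Among 10316 genes tested in all 3 comparisons, 102 fell with MRL-871 in both experiments and rose with Rorc, and 4 did the reverse. By strength of evidence the first 3 of the 102 were Gpr162, the interferon gamma receptor gene Ifngr1 (-0.57 in vitro, -0.99 in vivo, 3.70 in the line) and Sla (-1.58, -0.83 and 1.502), followed by Gtf2h4, Csrnp1, Bcl2l1, Slc43a2, Glcci1, Mr1 and Diexf. Csrnp1 was at -0.81, -0.81 and 1.70, and Glcci1 at -1.21, -1.54 and 2.54. In the overlap of the in vitro effect with the line, the transcription factor gene Nfatc3 was also among the first 10 (-0.63 and 0.76), and in that of the in vivo effect Plxnd1 (-1.89 and 1.62) and the cytokine receptor gene Il17re (-2.32 and 4.01) were. The 4 genes that rose with MRL-871 and fell with Rorc, named here after their values were seen, were Desi1, Dusp4, B4galt1 and Bid. Dusp4, a phosphatase gene acting on MAP kinases, was at 0.55, 0.48 and -2.59, and Bid was at 0.38, 0.35 and -0.40.

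**Figure D4:**
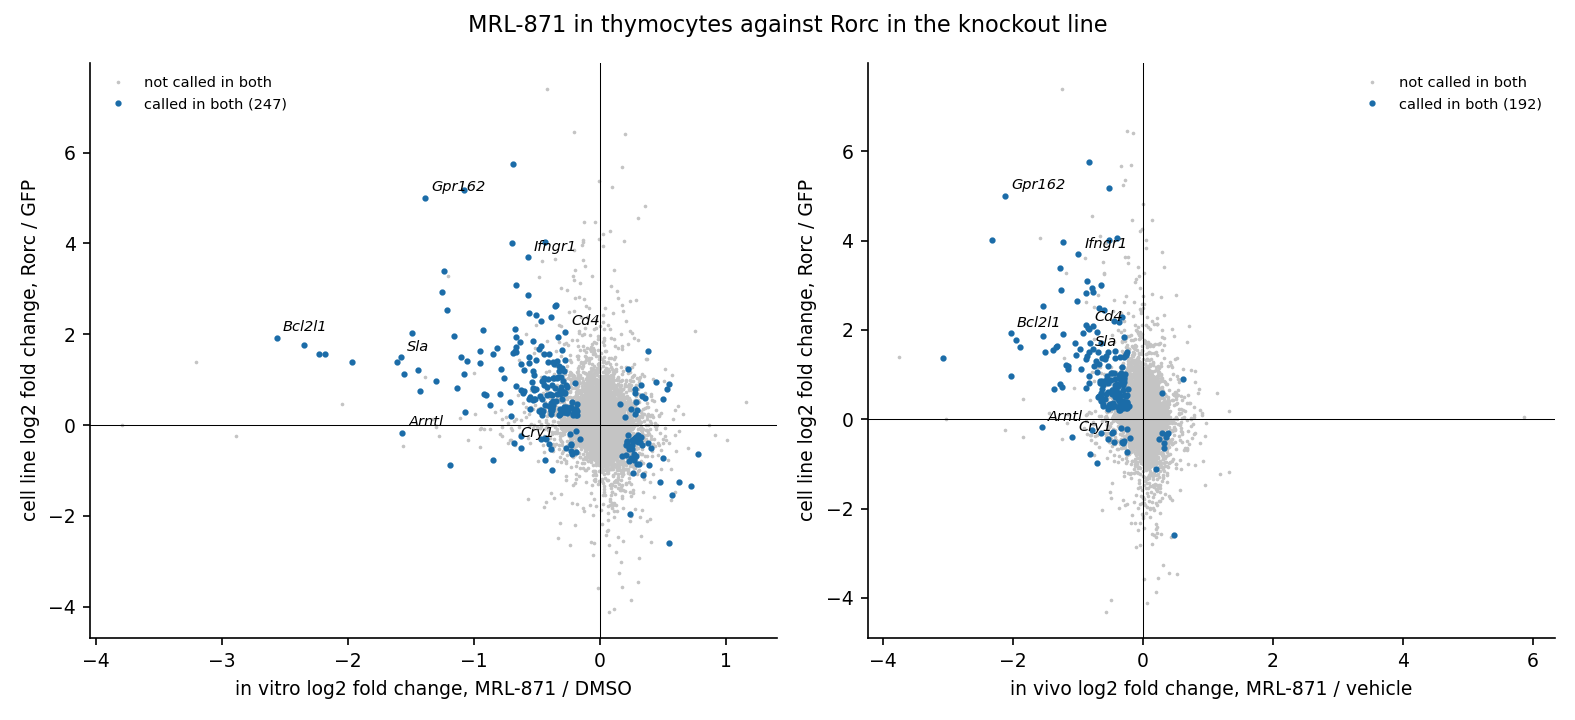
Log2 fold change with MRL-871 in vitro (left panel) and in vivo (right panel) on the horizontal axes against the log2 fold change with Rorc in the cell line on the vertical axes, 1 point per gene, with genes called in both in colour. Of the coloured genes, 208 of 247 on the left and 173 of 192 on the right have opposite signs.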

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

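All tests of the 3 patterns weighed here were chosen only after the results were seen. In 173 groups of 4 or 6 libraries tested for a library far from the rest, 12 were found, and chance gives about 1 in 20 groups, or 8.7. In vitro MRL-871 library 1 had 41.48M counts against 21.48M to 23.12M in the other 5. The share of reads removed as rRNA was 0.301% in MRL-871 library 5 in vitro (0.1455% to 0.1813% in the others), 0.6534% in DMSO library 2 (0.1486% to 0.2191%) and 1.514% in MRL-871 library 6 in vivo (0.1887% to 0.266%). DMSO library 1 lay below the other DMSO libraries in log2 CPM for B3gnt8 (3.349), Esrp2 (2.295) and E130304F04Rik (4.887). Other single libraries apart from their group in log2 CPM were in vitro MRL-871 library 4 for Rbm24 (-0.4959), vehicle library 3 for Npas2 (1.711), vehicle library 4 for Adamtsl2 (2.17), in vivo MRL-871 library 1 for E130304F04Rik (3.724) and cell line Rorc library 1 for Ankrd63 (3.504).

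The effect of MRL-871 differed between culture and animal by the interaction test for 19 named genes. The in vitro minus in vivo log2 difference was above 0 for Cdkl1 (4.358), Npas2 (1.769), Plxnd1 (1.219), Leprel4 (1.197), Slc7a11 (1.099), 2010015L04Rik (1.095), Atp10a (0.926), Dab2ip (0.907), Tube1 (0.715), Cd4 (0.56), Myc (0.508) and Cry1 (0.408). It was below 0 for Esrp2 (-1.395), Xkrx (-0.856), Cnn3 (-0.771), Sla (-0.76), Leo1 (-0.673), Bcl2l1 (-0.543) and Tnip1 (-0.525). Of these 19 genes, Cdkl1, Slc7a11, 2010015L04Rik, Dab2ip, Tube1, Esrp2, Xkrx and Sla carry the overlap mark.

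The first pattern was that the control libraries of the Rorc-knockout line held 51.8% of the Rorc level found with the vector. Cells carrying the Rorc vector among the controls are argued against, because the 10 genes that rose most with Rorc had a median control level of 2.31% of their level with Rorc (0.17% to 4.15%). Thymocytes with an intact gene are argued against as well: a share of 18.4% would be needed and would bring Cd8a to 307 CPM, and it was found at 0.964 CPM (levels set across tables normalised separately). The controls were sorted for GFP. Transcripts from the disrupted gene may remain, and counts per gene cannot decide this.

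The second pattern was that Arntl and Cry1 fell with MRL-871 and did not rise with Rorc in the line. Too few libraries is no sufficient reason, since the highest upper bound of the 95% intervals of both changes was -0.033, below 0 (Arntl -0.303 to -0.033, Cry1 -0.539 to -0.264). Cry1 carries no overlap mark in either table and fell by 0.401 on the log2 scale with Rorc (-0.401), so a marked overlap is no reason for it. Some unmarked features also overlap another by position. This was not looked up for Cry1, so overlapping reads are not excluded. A different clock phase of control and Rorc cells at collection stays open, because Dbp, which peaks opposite to Arntl, rose by 0.598 and no collection times were used here. A candidate biological explanation, that these genes need RORγt in thymocytes but not in this line, was not tested.

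The third pattern was that 42 genes had a higher log2 change in vitro than in vivo, of which 37 were called as fallen in vivo, 15 of them also in vitro. A fall in B cell, myeloid or erythroid cells is argued against for 23 of the 37, which fell by more than every one of 29 markers of these cells with all libraries (30 did; lowest marker -0.678; medians -1.094 and -0.234), without MRL-871 library 6 (29; -0.753; medians -1.067 and -0.468) and without libraries 2 and 6 (23; -0.876; medians -1.023 and -0.486), and stays open for the other 14. The in vivo MRL-871 libraries 2 and 6 are argued against as the source of most of the 58 differences, since 45 were called again without them. The 58 include differences in both directions, and how many of the 37 were among the 45 was not counted. A control level already lowered by culture is argued against for 10 of the 37 genes, Slc7a11 among them, which were higher in every DMSO than in every vehicle library. For 13 others, lower in every DMSO library, it may apply and cannot be told apart from other differences between the experiments. A stronger action of the compound in the animal on the 37 genes also stays open, as untested. Such an action would not cover every gene, since 16 of the 58 differences were below 0. Among them, Bcl2l1 (-0.543), Sla (-0.76) and Xkrx (-0.856) fell further in vitro.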

How the results depend on the processing

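The alternatives that left out features marked as overlapping, in vitro DMSO library 1 or chosen libraries in pairs were chosen only after the results were seen; the others were planned. No result reversed. Total counts outside 1.5 times the reported value came from smaller sets of libraries, genes or another test. Rises in vivo also moved in the fit of all 22 thymocyte libraries, with 70 in place of 33. In vitro, series A alone called 104 genes and series B alone 236. Each series had 3 libraries per treatment, and the cause of the difference between them was not tested. Without in vitro DMSO library 1, 565 genes were called. In vivo, 204 genes were called without marked features, as 127 of the 332 carried the mark (38.3% against 32.4% of genes not called, Fisher's exact p = 0.0281, 0.112 after BH over 4 comparisons), and rises, 33 with all libraries, numbered 13 to 96 with 1 library left out. The interaction gave 91 genes with DESeq2, for which the cause was not tested, and 38 without marked features. Genes shared in vitro and in vivo numbered 120, and those called in vivo and oppositely in the line 108, without marked features. With an estimated correlation, 0 lists were called in vitro, 1 in vivo and 0 in the line. Without marked features, 2 lists were called in vitro and 4 in vivo, and 4 in vivo without MRL-871 libraries 2 and 6 (for these the cause was not tested). Leaving out 1 library at a time gave 225 to 474 genes in vivo, 3586 to 4520 in the line and 39 to 86 for the interaction. It gave 3 to 9 lists in vivo (4 without vehicle library 3, 3 without MRL-871 library 1, 4 without library 2, 3 without library 4) and 7 to 8 in the line. Shared genes ranged from 147 to 190 in vitro and in vivo, 181 to 203 in vitro against the line and 121 to 239 in vivo against the line. Among 1261 alternative values of named genes in vitro, 45 lost and 16 gained a call; in vivo 63 and 45 of 2107; in the line 62 and 12 of 1560; for the interaction 19 and 0 of 325. The effect of depth itself was not tested; at the depths and spreads of these libraries, 82.1% of simulated 1.5-fold changes were recovered in vitro and 64.2% in vivo and in the line. No paired analysis was possible because replicate numbers only follow accession order.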

Other observations

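The regroupings of libraries in this part were planned, and no test here was chosen only after the result was seen. Positive selection genes in vitro had 1 of 15 members higher, Id3, and 1 lower, the scavenger receptor gene Cd6 (-0.44), and in vivo 1 higher, Itm2a, and 2 lower, Cd6 (-0.52) and Gata3 (-0.25, lost in 3 of 16 alternatives with adjusted p up to 0.0907), with camera adjusted p = 0.268 and 0.779. In the line Cd6 rose (4.02) while Tox (-0.84), Gata3 (-0.74) and the TCR-induced receptor gene Nr4a1 (-1.49) fell (camera adjusted p = 0.148). The double-negative list had 1 of 12 members lower in vivo, Ptcra (-0.36, camera adjusted p = 0.577), and in the line 1 of 7 higher, the Notch target Dtx1 (1.88), and 4 lower, among them Hes1 (-0.75, camera adjusted p = 0.641). TH17 genes had 0 of 8 called in vitro (camera adjusted p = 0.772) and 1 of 9 lower in vivo, Rorc (0.433). In the line 2 of 5 rose, Irf4 (1.54) and Rorc, whose rise was set by the vector, and Batf fell (-1.46, camera adjusted p = 0.383).

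In the line, 4 of 7 LXR targets rose, among them Abcg1 (0.86) and Lpcat3 (0.50, camera adjusted p = 0.204), against 0 of 9 called in vitro (0.573). The clock list in the line had 4 of 16 members higher, Dbp, Tef (0.59), Clock (0.45) and Rorc, whose rise was set by the vector. It had 2 lower (camera adjusted p = 0.438), and 10 of the 16 had a positive change. Recombination machinery had 6 of 12 members higher and 3 lower in the line (0.148) and 1 of 12 higher in vivo, Xrcc6 (0.30, lost in 8 of 16 alternatives with adjusted p up to 0.8; camera adjusted p = 0.993). The TCR alpha variable list was not called in vivo (0 of 9, camera adjusted p = 0.786) and had no member in the cell line table, nor had mitochondrially encoded genes.

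The remaining lists were not called by camera. In vitro the camera adjusted p was 0.573 for mature thymocyte, 0.54 for cholesterol synthesis, 0.766 for glycolysis (1 of 17 lower, Pfkp), 0.061 for DNA replication, 0.195 for mitosis, 0.54 for p53 (1 of 14 higher, Trp53inp1, lost in 4 of 9 alternatives with adjusted p up to 0.797) and 0.54 for heat shock genes. It was 0.573 for immediate early (1 of 13 lower, Zfp36), 0.376 for glucocorticoid, 0.683 for interferon (1 of 17 lower, Ifit2), 0.766 for E and ID protein, 0.721 for B cell, 0.061 for myeloid, 0.772 for stroma, 0.195 for NK and 0.66 for replication histone genes. In vivo it was 0.438 for mature thymocyte, 0.809 for cholesterol synthesis, 0.577 for glycolysis (1 of 17 lower, Pfkp), 0.117 for DNA replication, 0.226 for mitosis, 0.355 for p53 and 0.6 for heat shock genes. It was 0.637 for ER stress, 0.438 for immediate early (1 of 13 lower, Zfp36), 0.226 for glucocorticoid, 0.993 for interferon, 0.368 for E and ID protein, 0.744 for stroma, 0.368 for erythroid, 0.226 for NK and 0.226 for replication histone genes. In the line it was 0.761 for mature thymocyte (1 of 5 higher, 1 lower), 0.498 for DNA replication (3 of 18 higher), 0.761 for p53 (3 of 12 higher, 3 lower), 0.241 for immediate early (4 of 13 higher) and 0.416 for glucocorticoid genes (2 of 8 higher, 1 lower). It was 0.227 for interferon (4 of 10 higher, 1 lower), 0.472 for E and ID protein (1 of 6 lower), 0.731 for myeloid (1 of 3 higher) and 0.906 for replication histone genes (4 of 47 higher). Erythroid markers in vitro and stroma markers in the line had 2 tested members each, too few for the list test, with 0 called, and fewer than 3 B cell and erythroid markers were tested in the line. Median, mean and test did not share a sign for BCL2 family, B cell, TH17 and glycolysis genes in vitro, for double-negative, cholesterol, ER stress, E and ID protein and erythroid genes in vivo, and for p53 targets in the line.

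Other splits of the libraries into groups of the same sizes were refitted for every count. A chance split of these libraries could be excluded for the 442 genes called in vitro (highest of 100 splits otherwise 64), the 332 in vivo (13) and the 4576 in the line (0 in 84 splits). The splits treat each library as a separate unit, which the labels do not state. They therefore cover only the spread between libraries, and not a difference shared by all libraries of a group. In each case 1 split was as large, the real one. The real split was also the only 1 as large for the 181 genes shared in vitro and in vivo (0 otherwise). The same held for the 208 and 173 genes called oppositely in the line (0 each otherwise). These overlaps add nothing to the 332 and the 4576. The other splits of the line called 0 genes to share, and those in vivo at most 13. For the number of called lists chance could not be excluded: as many were called in 69 of 100 splits in vitro (6 real, at most 15), 61 of 100 in vivo (7, at most 17) and 8 of 84 in the line (8, at most 11). For the 58 interaction genes 3 of 100 splits were as large, the real one included. This does not exclude chance or a structure of the samples, because another split called 563 genes. Of the other 2, 1 called 178 genes but kept all 6 in vivo MRL-871 libraries against all 4 vehicle libraries and mixed only the in vitro ones, so it held the in vivo effect. The highest other split called 563 genes, which points to a structure of the samples, and put in vitro MRL-871 libraries 1, 3 and 6 with DMSO libraries 1, 4 and 5, and in vivo vehicle libraries 3 and 4 with MRL-871 libraries 1, 3, 4 and 5. In vivo MRL-871 libraries 2 and 6, which it sets apart with vehicle libraries 1 and 2, are those that stood apart in the in vivo comparison.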
